A study of Homo sapiens with 2 samples.

How the data were processed

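RNA was extracted with TRIzol from HEK293T cells with a stable FKBP5 knockdown, and directional libraries were prepared from total RNA with a modified NEBNext protocol, per the labels' protocols. The data analysed here are 1 table of gene counts with a column for each of 2 samples, and 1 file of CPM for each sample. Both samples belong to the group FKBP5 knockdown by their genotype label, and the replicate numbers come from their titles. The extraction protocol also mentions cells with a scrambled control, which were not analysed here, so the planned comparisons of knockdown with control were not made and no test of a knockdown effect was run.

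The deposited counts are whole numbers per Ensembl gene, with no normalization, and no row lacks a gene. The submitters' processing notes name STAR 2.7.7a, edgeR and the genome build GRCh38. The counting program, its strand setting, its treatment of reads that fit several genes and the annotation are not given in the sources used here. The deposited CPM equal the counts times 1 constant per library: 100% of values were whole reads within a tolerance of 1e-06. The library size behind them was 3.78% above the column total in sample 1 and 2.68% above it in sample 2, so the CPM summed to 963583 and 973939. How that library size was set is not given in the sources used here. The count table lists 60683 genes and the CPM files 44279. The 16404 genes left out had no count in either sample, and 2954 genes with no count were kept.

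Depth was 9997706 counts in sample 1 and 21284648 in sample 2, with 31310 and 38571 genes counted at least once. Intervals are 95% exact Poisson intervals for the CPM of a gene and Wilson intervals for a share of counts. The floor is the level of 3 counts, 0.289 CPM in sample 1 and 0.137 CPM in sample 2. Reads carry no stated molecular identifiers, so intervals and floors cover counting error only. A gene at the FKBP5 level is therefore known less precisely in sample 1 than in the deeper sample 2.

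Gene symbols were found for 99.5% of the gene IDs, and 96.4% were in GENCODE 29 (GRCh38), which gave coordinates and classes. The IDs outside it mean that the authors' annotation differs from GENCODE 29, so genes that overlap there may not be those that overlapped in their counting. Means and SD are over the 2 deposited CPM values. Log2 ratios are log2 of (CPM + 1) of sample 2 over that of sample 1, which understates the ratio of low genes, and use genes with a mean of at least 1 CPM. The 2-sided exact binomial test compared each gene's counts with the share of reads set by the deposited scaling, with Benjamini-Hochberg adjustment over 15530 genes. It includes no variation between cultures, so it calls small differences in abundant genes. The common dispersion was estimated with edgeR 4.0.16 (filterByExpr, TMM) in R 4.3.3. Other steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and statsmodels 0.14.6.

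The 36 gene lists (1178 genes) were written before the data were examined. They include markers of epithelial lines, blood cells and fibroblasts, cells that the culture should not contain. Of the names in the lists, 91 matched no gene ID in the table, older symbols that duplicate a current one included. A list's median log2 ratio was set against 10000 random lists of the same size matched on mean CPM in 20 bins. Named genes followed a rule fixed at the same time: FKBP5, the 15 genes with the highest mean CPM, and of each list the 2 members with the highest mean CPM. A gene that the rule selects is not reported here. Genes outside this rule are said to have been chosen after their values were seen.

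Both statistics were tested on simulated data with the real genes and depths. In 15530 genes of which 200 were changed, the binomial test recovered 73% of 1.5-fold changes, with 4 unchanged genes past it, and 81% of 2-fold changes, with 3 unchanged genes past it. These counts were drawn with Poisson counting error only, which the test assumes. They therefore give no error rate for the real libraries, which vary by more than counting error. A simulated coefficient of variation of 5% was estimated as 5.01%. Alternatives were another CPM minimum, pseudocount, scaling and filter, and leaving out each sample in turn. Reads shared between genes were assessed from GENCODE 29 by same-strand overlap of exons and by the share of 50-base stretches found in no other gene's transcript.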

Results

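RNA-seq libraries were made from HEK293T cells, a human embryonic kidney line that expresses the SV40 large T antigen, after stable knockdown of FKBP5 with short hairpin RNAs. FKBP5 encodes an immunophilin that binds HSP90 and holds steroid receptors in a state of low affinity for hormone. The series title sets out to find genes whose expression differs after the knockdown. The samples analysed here form 1 group of 2 FKBP5 knockdown samples, and control cells were not analysed here. The report therefore gives levels in the knockdown cells and the difference between the 2 samples, and no change caused by the knockdown. Sample 1 held 9997706 counts and sample 2 held 21284648. Nothing in the labels says that the 2 samples came from separate cultures, so the spread between them may be technical. Levels are the deposited CPM (counts scaled to library size and not to transcript length). Between genes they compare counts and not numbers of molecules. A gene's level is given as mean ± SD over the samples (n = 2), and intervals cover counting error only.

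FKBP5 transcripts were still measured in both knockdown samples, at a low level. The gene had 41 counts in sample 1 and 77 in sample 2. These were 3.95 CPM in sample 1 (95% exact Poisson interval 2.84 to 5.36) and 3.52 CPM in sample 2 (2.78 to 4.40), a mean of 3.74 ± 0.303 CPM. The samples did not differ in FKBP5 by an exact binomial test between the libraries (adjusted p = 0.863). FKBP5 (ENSG00000096060) lies on chromosome 6, from 35573585 to 35728583 on the minus strand (GRCh38, GENCODE 29), where its exons overlap no other gene's on that strand and 99.3% of its 50-base stretches occur in no other gene's transcript. Of the 15530 genes with a mean of at least 1 CPM, 19.7% lay below it.

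FKBP5 ranked 12 among 14 FKBP genes, tabulated after the values were seen. These were FKBP5 and the FKBP genes in the list of HSP90 chaperones, co-chaperones and immunophilins, and not every gene of the family. FKBP8, which is anchored in the outer mitochondrial membrane, was highest at 466 ± 10.4 CPM, which was 125 times the FKBP5 level. FKBP10, a collagen chaperone of the endoplasmic reticulum, had 395 ± 3.02 CPM. FKBP4, the closest paralog of FKBP5 and also an HSP90 co-chaperone, had 258 ± 16.6 CPM, which was 69.0 times the FKBP5 level. FKBP1A, a rapamycin-binding member, had 231 ± 3.74 CPM. FKBP1B, 27.7% of whose exonic bases lie in exons of another gene on the same strand, had 2.80 ± 0.136 CPM. FKBP2 had no count in sample 1 (upper end of the exact Poisson interval 0.356 CPM) and 3 counts in sample 2. Loss of reads was not excluded for FKBP1B and FKBP2, the only ones of the 14 below FKBP5, so the rank of FKBP5 is uncertain. The extent of the FKBP5 knockdown cannot be read from these levels, because control cells were not analysed here.

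**Figure D1:**
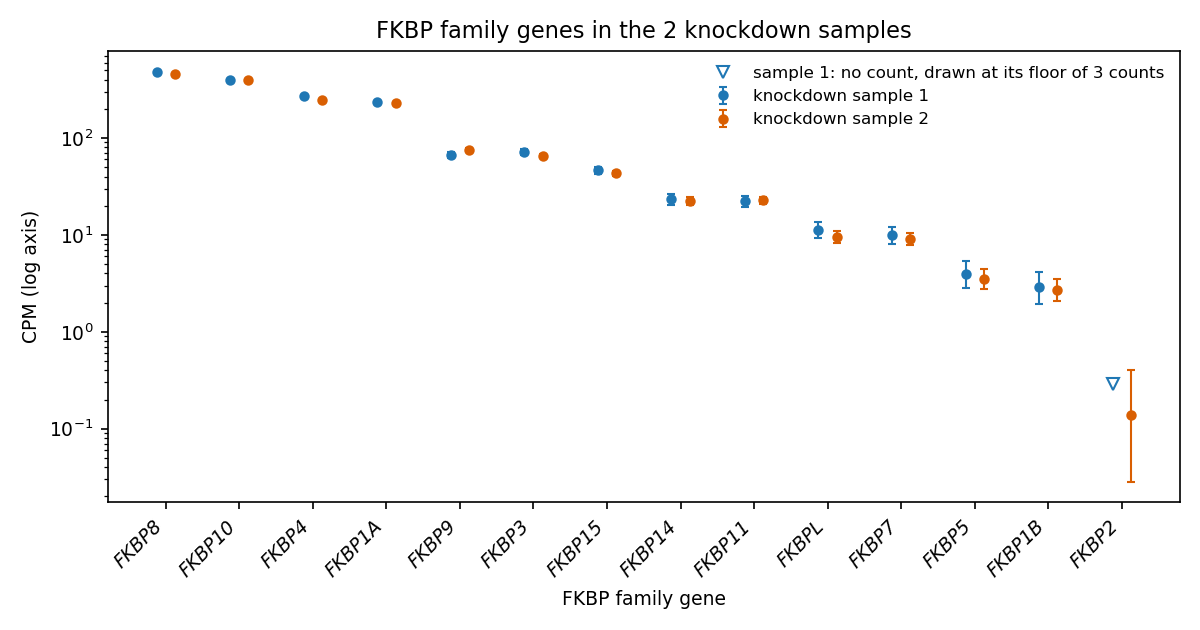
CPM (log axis) of 14 FKBP genes in knockdown samples 1 and 2, with 95% exact Poisson intervals; the open triangle marks FKBP2 in sample 1, which had no count and is drawn at the floor of 3 counts (0.289 CPM). FKBP5 sits at 3.95 and 3.52 CPM, below FKBP8, FKBP10, FKBP4 and FKBP1A, which all lie above 200 CPM.

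The genes with the highest CPM were mainly those of the mitochondrial genome and the translation machinery. MT-CO1, a subunit of cytochrome c oxidase, led with 20494 ± 3640 CPM, followed by the large mitochondrial ribosomal RNA MT-RNR2 at 10709 ± 1535 CPM. MT-CO2 had 7439 ± 1074 CPM, MT-ND4 6041 ± 820 CPM, MT-ATP6 4523 ± 527 CPM, MT-CO3 4142 ± 0.938 CPM, MT-ND5 3832 ± 345 CPM and MT-CYB 3572 ± 135 CPM. The elongation factors EEF1A1 and EEF2 had 7309 ± 430 and 6006 ± 369 CPM. The ribosomal protein genes RPS2 and RPS4X had 5089 ± 71.0 and 2664 ± 73.0 CPM. The cytoplasmic actins ACTG1 and ACTB had 3172 ± 8.42 and 2848 ± 123 CPM. XIST, the long non-coding RNA of X inactivation, had 6397 ± 1643 CPM. These 15 genes with the highest mean CPM took 9.01% of counts in sample 1 and 10.4% in sample 2.

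By class of transcript, nuclear protein-coding genes held most counts, with 91.0% in sample 1 and 89.6% in sample 2. The mitochondrial genome held 6.47% in sample 1 (95% Wilson interval 6.45 to 6.48%) and 7.57% in sample 2 (7.56 to 7.59%), a ratio of 1.17. XIST alone held 0.543% and 0.776%, a ratio of 1.43. Long non-coding RNAs, XIST included, held 1.66% and 1.95%, and pseudogenes 0.686% and 0.755%. Small RNA classes with nuclear ribosomal RNA held 0.0342% and 0.0306%. At least 1 CPM was reached by 15364 genes in sample 1 and 15740 in sample 2, of which 15022 did so in both. The exact Poisson interval of a count of 0 reached 0.356 CPM in sample 1 and 0.169 CPM in sample 2.

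The HSP90 genes were among the more abundant, and their co-chaperones and the immunophilins ranged widely. Of 40 genes for HSP90 chaperones, co-chaperones and immunophilins, fixed before the data were examined with FKBP5 left out, 39 had at least 1 CPM and 23 at least 100 CPM. Their median was 180 ± 10.7 CPM, where the SD of a list is that between the medians of the 2 samples. A list's median is taken over its members' mean CPM, so it can lie outside the medians of the 2 samples. The SD is then no spread around it. The cytosolic HSP90 genes led, with HSP90AA1 at 2521 ± 71.5 CPM and HSP90AB1 at 1514 ± 37.96 CPM. The heat shock response list, which holds the same HSP90 genes, had a median of 148 ± 7.97 CPM over 28 genes. Genes that glucocorticoids induce had a far lower median of 11.6 ± 2.69 CPM, and 8 of 31 were under 1 CPM. TSC22D3, a leucine zipper protein induced by glucocorticoids, stood out among them at 1209 ± 19.2 CPM, while the clock gene PER1 had 103 ± 4.74 CPM.

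Inflammatory and interferon genes were low. NF-kappaB targets had a median of 6.998 ± 0.00773 CPM (7.04 in sample 1 and 7.05 in sample 2), and 10 of 27 were under 1 CPM. NFKB2, a precursor subunit of NF-kappaB, led with 99.02 ± 4.27 CPM, followed by TNIP1 at 95.1 ± 0.529 CPM. Interferon-stimulated genes had a median of 4.90 ± 0.0502 CPM (4.58 in sample 1 and 4.51 in sample 2), with 11 of 44 under 1 CPM. LGALS3BP, a secreted glycoprotein, was the exception at 679 ± 12.995 CPM, and STAT2, a transducer of interferon signals, had 56.6 ± 1.78 CPM. Blood cell markers had a median of 0.326 ± 0.0186 CPM (0.386 in sample 1 and 0.412 in sample 2), with 12 of 18 under 1 CPM. The highest were CORO1A at 17.97 ± 1.85 CPM and HLA-DRB1 at 10.4 ± 0.579 CPM.

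Genes of stress pathways were expressed at intermediate to high levels. With no control cells analysed, these levels do not show whether a pathway was active. Targets of ATF4 in the integrated stress response had a median of 63.7 ± 4.18 CPM, led by the serine synthesis enzyme PHGDH at 664 ± 19.5 CPM and by ATF4 itself at 537 ± 19.6 CPM. Chaperones of the unfolded protein response had a median of 50.7 ± 0.928 CPM, with HSPA5 at 836 ± 95.2 CPM and CALR at 667 ± 56.3 CPM. The p53 targets had a median of 33.0 ± 0.610 CPM, with CCNG1 at 135 ± 7.31 CPM and BAX at 115 ± 4.96 CPM. NRF2 targets had a median of 39.2 ± 3.60 CPM, with the transketolase gene TKT at 667 ± 8.41 CPM and the ferritin light chain gene FTL at 401 ± 8.74 CPM. Hypoxia targets had a median of 36.9 ± 0.0414 CPM, with PGK1 at 409 ± 17.1 CPM and LDHA at 371 ± 36.9 CPM. SnoRNA host genes and other transcripts sensitive to nonsense-mediated decay had a median of 45.9 ± 0.909 CPM, with ATF4 and SMG5 (318 ± 5.37 CPM) highest.

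Metabolic genes ranged from intermediate to high levels. Glycolysis had a median of 162 ± 1.60 CPM, and all 21 members had at least 1 CPM. ENO1 had 2465 ± 170 CPM and PKM 2007 ± 185 CPM. Fatty acid synthesis had a median of 85.8 ± 5.49 CPM, with the fatty acid synthase gene FASN at 1668 ± 35.9 CPM and the desaturase gene SCD at 643 ± 12.5 CPM. Cholesterol biosynthesis and uptake had a median of 40.9 ± 3.85 CPM, with the regulator SREBF2 at 245 ± 20.3 CPM. Nuclear genes of oxidative phosphorylation had a median of 54.4 ± 4.64 CPM over 72 genes, with the ATP synthase genes ATP5F1B at 1056 ± 49.4 CPM and ATP5F1A at 382 ± 17.7 CPM. The 15 mitochondrially encoded genes had a median of 3572 ± 135 CPM.

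Genes of growth and division were expressed in nearly full number. All 39 genes of the G1/S and DNA replication list and all 40 of the G2/M and mitosis list had at least 1 CPM. Their medians were 81.3 ± 1.70 and 88.4 ± 3.48 CPM. The helicase gene MCM7 had 440 ± 12.2 CPM, the DNA polymerase gene POLE 354 ± 8.20 CPM, the topoisomerase gene TOP2A 458 ± 1.03 CPM and the proliferation marker MKI67 396 ± 20.96 CPM. Cytosolic ribosomal proteins had a median of 493 ± 2.66 CPM over 77 genes. MYC targets and genes of ribosome biogenesis had a median of 103 ± 7.30 CPM, led by NCL at 1429 ± 42.2 CPM and NPM1 at 1090 ± 56.8 CPM. SR proteins and hnRNPs had a median of 239 ± 18.4 CPM, led by HNRNPA2B1 at 1358 ± 77.8 CPM and HNRNPA1 at 1154 ± 3.05 CPM. Of RPS2 and NPM1, 56.7% and 55.3% of the 50-base stretches in their transcripts were found in no other gene, so reads shared with near-identical copies make these levels uncertain.

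Replication-dependent histone genes and small structural RNAs were near the floor. Of 54 histone genes, 39 were under 1 CPM and 10 had no count in either sample, and the median was 0.283 ± 0.0929 CPM. The highest were H1-2 at 10.3 ± 0.343 CPM and H4C9 at 7.78 ± 0.584 CPM. The histone gene H2BC12, outside the list and named after its values were seen, was higher at 51.0 ± 2.198 CPM. Of 31 abundant small nuclear and cytoplasmic RNAs, 20 had no count in either sample. RN7SL1, the RNA of the signal recognition particle, reached 48.5 ± 16.7 CPM, and SNORD3A, the U3 small nucleolar RNA, 0.538 ± 0.0799 CPM. RN7SK, RMRP and RPPH1, named after their values were seen, had no count. Whether reads of these small RNAs were lost to copies or overlapping genes was not tested. A lack of counts therefore need not mean that the RNA was absent.

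Regulatory lists lay between these extremes. Notch targets had a median of 76.7 ± 6.16 CPM, with HES4 at 368 ± 20.2 CPM and the receptor gene NOTCH3 at 325 ± 40.4 CPM. Targets of FOXO factors that AKT restrains had a median of 29.4 ± 1.51 CPM, with the cell cycle inhibitor gene CDKN1B at 113 ± 3.14 CPM and FOXO3 at 104 ± 5.97 CPM. YAP and TGF-beta targets had a median of 22.2 ± 1.499 CPM, with ID2 at 126 ± 5.17 CPM and FSTL1 at 120 ± 6.40 CPM. Wnt targets had a median of 17.2 ± 1.19 CPM, with the cyclin gene CCND1 at 160 ± 0.962 CPM and SOX4 at 129 ± 0.974 CPM. Immediate early genes had a median of 12.7 ± 0.895 CPM, with JUN at 236 ± 61.0 CPM and JUND at 208 ± 26.1 CPM. Circadian clock genes had a median of 12.1 ± 1.16 CPM, with PER1 and BHLHE40 (80.8 ± 2.52 CPM) highest. Autophagy and lysosome genes had a median of 51.7 ± 0.299 CPM, with PSAP at 593 ± 18.9 CPM and LAMP1 at 205 ± 7.23 CPM. KRAB zinc finger genes had a median of 5.40 ± 0.360 CPM over 80 genes, with ZNF74 at 82.4 ± 0.327 CPM and ZNF212 at 45.9 ± 1.04 CPM.

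**Figure D2:**
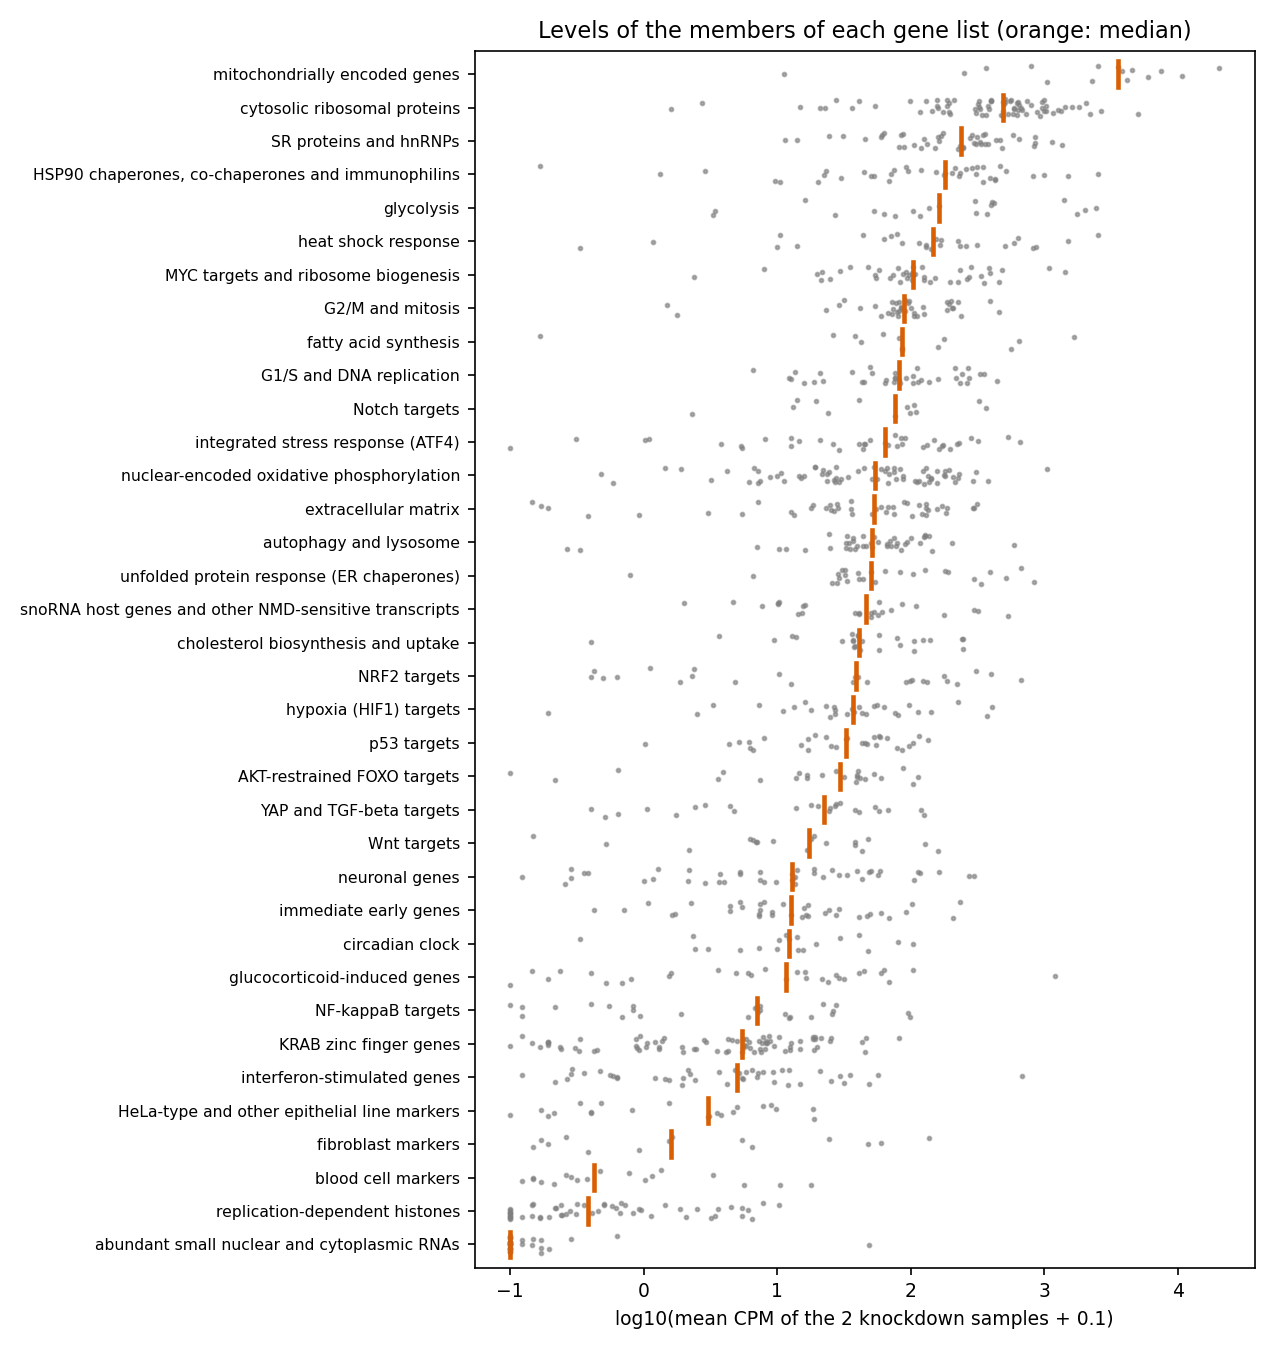
Each grey point is a member of a gene list at its mean CPM over both knockdown samples, plotted as log10(CPM + 0.1), and each orange bar is the list's median. Medians run from 3572 CPM for the mitochondrially encoded genes to 0.283 CPM for the replication-dependent histones and 0 for the small nuclear and cytoplasmic RNAs.

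The 2 knockdown samples had closely similar profiles. Over the 15530 genes with a mean of at least 1 CPM, the SD of the log2 ratio of CPM + 1 was 0.21 (95% bootstrap interval over genes 0.20 to 0.21). By the same ratio of CPM + 1, 98.3% of genes were within 1.5-fold. Pearson's r of log2(CPM + 1) was 0.995 across genes, which are not independent replicates. The biological coefficient of variation that edgeR estimated from the 2 samples was 5.64%. Counting error alone did not account for the spread, since chi-square over its degrees of freedom was 4.66. The SD of the log2 ratio was 0.28 over the 5215 genes at 1 to 10 CPM and 0.11 over the 2282 genes at 100 CPM and over.

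An exact binomial test of the counts, 2-sided, compares these libraries and not conditions. It separated them for 1353 of 15530 genes at an adjusted p under 0.05 (Benjamini-Hochberg), 667 higher in sample 2 and 686 lower. With CPM scaled to the column totals the split was 569 higher and 885 lower. Only 102 of the 1353 differed by at least 1.5-fold in CPM + 1, 90 of them higher in sample 2. This measure understates the ratio of low genes. XIST (1.44-fold by CPM), MT-CO1 (1.29-fold) and MT-CO2 (1.23-fold) were higher in sample 2. The immediate early gene JUN had 192 CPM in sample 1 and 279 CPM in sample 2, and JUND 189 and 226 CPM. RN7SL1 was lower, with 60.3 and 36.7 CPM. ACTG1, MT-CO3, TOP2A and HNRNPA1 did not pass the test, and neither did TSC22D3, at 1195 and 1222 CPM.

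**Figure D3:**
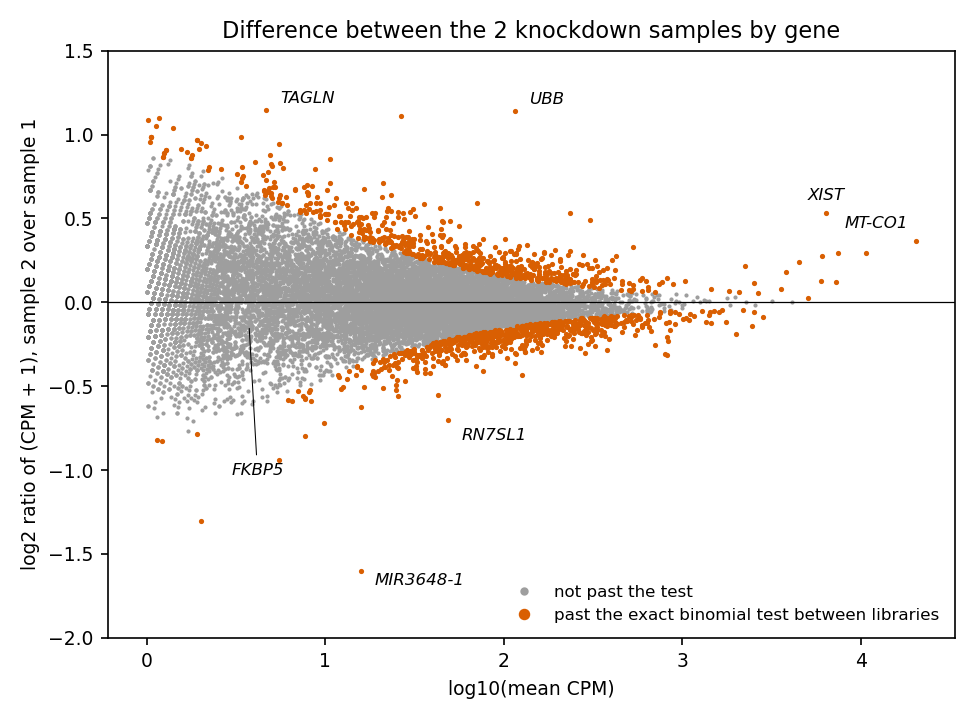
Log2 ratio of CPM + 1, sample 2 over sample 1, against log10 mean CPM for the 15530 genes with a mean of at least 1 CPM; orange points are the 1353 genes past the exact binomial test between the libraries. The 2 samples scatter around 0 and FKBP5 lies inside the cloud at a log2 ratio of -0.13.

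Some gene lists differed as a whole between the 2 libraries. Extracellular matrix genes were higher in sample 2, with a median log2 ratio of 0.15 over 39 genes and 37 of them higher. Of these, 12 passed the binomial test, all higher in sample 2, and 20 did so when adjusted over the list alone. The laminin gene LAMC1 had 298 CPM in sample 1 and 325 CPM in sample 2, and AGRN, which encodes agrin, 277 and 320 CPM. The mitochondrially encoded genes had a median log2 ratio of 0.12, with 8 of 15 past the test and higher in sample 2 and 2 lower (10 and 2 adjusted over the list alone). Both medians lay above those of all 10000 random lists matched on mean CPM. For the mitochondrially encoded genes the match was loose, since the highest of the 20 bins held JUND (208 CPM) as well as MT-CO1 (20494 CPM).

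MYC targets and genes of ribosome biogenesis were lower in sample 2, with a median log2 ratio of -0.15 over 44 genes. Of these, 24 passed the test and were lower and 1 was higher (27 and 1 adjusted over the list alone). NCL had 1459 CPM in sample 1 and 1400 CPM in sample 2, and NPM1 1130 and 1050 CPM. Chaperones of the unfolded protein response had a median of -0.12, with 7 lower and 1 higher (11 and 1 adjusted over the list alone). HSPA5 had 903 and 768 CPM, and CALR 707 and 627 CPM. Nuclear genes of oxidative phosphorylation had a median of -0.08, with 9 lower and 1 higher (12 and 1 adjusted over the list alone). HSP90 chaperones, co-chaperones and immunophilins had a median of -0.07, with 11 lower and 0 higher (13 and 1 adjusted over the list alone).

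In all, 14 of 35 lists had a median ratio outside the central 95% of random lists, 3 above and 11 below. Random lists are drawn as if the members of a list varied independently. No adjustment was made for the number of lists, some of which share genes, so the count of 14 may be too high. Notch targets (0.09) were the other list above, with NOTCH3 at 296 CPM in sample 1 and 354 CPM in sample 2. The others below were histones (-0.14, with no gene past the test), NRF2 targets (-0.09), glycolysis (-0.08), KRAB zinc finger genes, G2/M genes and SR proteins and hnRNPs (all -0.07) and G1/S genes (-0.06). Of the glucocorticoid-induced genes, at a median of 0.03, 1 of 23 passed the test and 0 did so adjusted over the list alone. NF-kappaB targets, at 0.02, had none past either test, and interferon-stimulated genes had 1 lower in both. All 3 lists lay inside the range of random lists. After correction for GC content and transcript length 8 of the 35 were outside: extracellular matrix, mitochondrially encoded genes, MYC targets, the unfolded protein response, oxidative phosphorylation, histones, NRF2 targets and KRAB zinc finger genes. The HSP90 list was then inside, at the percentile 4.08 of random lists where it had been at 0.15, although its median was -0.07 before and after. Of the other lists then inside, only Notch targets had a much smaller median, 0.04. The medians of glycolysis (-0.08), G1/S genes, G2/M genes and SR proteins and hnRNPs (all -0.06) stayed about as large, so the correction did not remove these differences. The share of counts from the mitochondrial genome and XIST was also higher in sample 2, as given above.

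**Figure D4:**
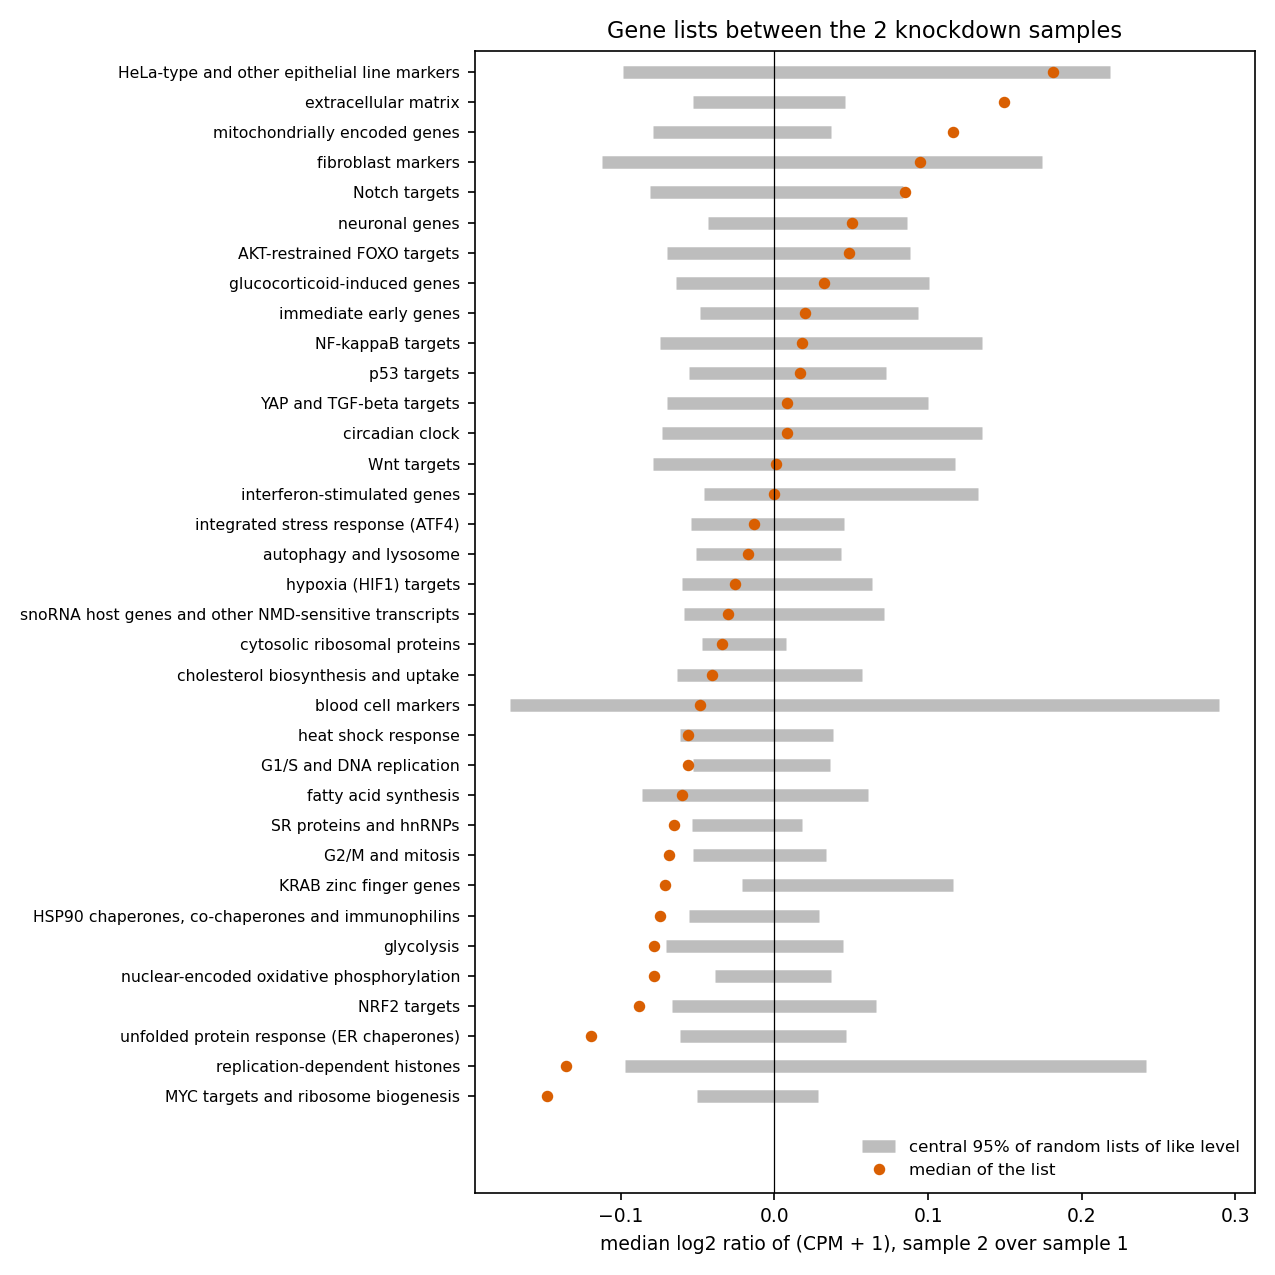
Median log2 ratio of CPM + 1, sample 2 over sample 1, for 35 gene lists (orange points) and the central 95% of medians of 10000 random lists of the same size matched on mean CPM (grey bars). Extracellular matrix genes (0.15) and mitochondrially encoded genes (0.12) lie above their bars, and MYC targets and ribosome biogenesis (-0.15) below.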

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

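The alternatives for the coefficient of variation, the binomial test, the ratios of the lists, the named genes and the share of the mitochondrial genome were chosen after the data were seen, and the others before. No alternative for knockdown against control was run, because control cells were not analysed here: thresholds, DESeq2, filters, list tests and left-out replicates of that comparison have no values. No paired analysis was possible because the samples form 1 group. The SD of the log2 ratio between the samples, 0.21, became 0.27 with a pseudocount of 0.1, 0.13 with a pseudocount of 5 and 0.19 with no filter, since the pseudocount sets how far low genes spread. Scaling by the median ratio left it at 0.21. At CPM minima of 0.5 and 2, 17510 and 13732 genes were detected in sample 1 and 18308 and 13883 in sample 2. The binomial test gave 1454 genes with the column totals and 942 over all genes with a count. The coefficient of variation stayed between 5.62% and 5.65%, and the share of the mitochondrial genome was 6.47 or 7.57% with a sample left out. Leaving out each sample moved the medians of 10 lists past the SD between the samples. For 4 lists the median over both samples lay between those of the single samples. These were fatty acid synthesis (79.8 to 87.6 CPM), ribosomal proteins (492 to 496), circadian clock (10.99 to 12.6) and KRAB zinc finger genes (5.03 to 5.54). For the others it lay outside. Heat shock response had 148 CPM over both samples and 149 to 160 in single samples, and snoRNA hosts 45.93 and 44.6 to 45.88. Neuronal genes had 12.9 and 12.1 to 12.4, and NF-kappaB targets 6.998 and 7.04 to 7.05. Interferon-stimulated genes had 4.90 and 4.51 to 4.58, and blood cell markers 0.326 and 0.386 to 0.412. The medians of a list move because its middle gene changes. The mean of FKBP5 stayed between 3.52 and 3.95 CPM. With the column totals, 28 of the 80 named genes moved by more than the SD, and every named gene rose by 3.13 to 3.36%. The rest of the 240 values of named genes came from leaving out a sample. With 2 samples that cannot move a gene's mean past their SD, so these values test nothing. None of the 70 list ratios left its bootstrap interval, but with a pseudocount of 5 the median log2 ratio of KRAB zinc finger genes shrank from -0.07 to -0.03 and that of histones from -0.14 to -0.09. Depth limits genes of few counts most: FKBP5 rests on 41 and 77 counts.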

Other observations

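The test of polyadenylated RNA, the tests by principal transcript length, the test by overlap in general, and the tests of cells of another type were chosen only after the results they bear on had been seen; the others were set before their values were computed. Neuronal genes were widely expressed in these cells: 38 of 45 had at least 1 CPM and 24 at least 10 CPM. Their median was 12.9 ± 0.217 CPM (12.4 in sample 1 and 12.1 in sample 2). The neurofilament gene NEFL had 297 ± 11.7 CPM and the ubiquitin hydrolase gene UCHL1 273 ± 13.4 CPM. Extracellular matrix genes had a median of 52.9 ± 4.14 CPM, with 36 of 44 at 10 CPM or more, LAMC1 at 312 ± 18.5 CPM and AGRN at 299 ± 30.1 CPM. Markers of other cell types were low. Those of HeLa-type and other epithelial lines had a median of 2.92 ± 0.428 CPM, with CAV2 at 19.0 ± 1.99 CPM and CAV1 at 18.6 ± 1.64 CPM. Fibroblast markers had a median of 1.498 ± 0.211 CPM, although FBLN1 reached 136 ± 10.7 CPM and COL1A1 59.7 ± 8.10 CPM.

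Some genes differed far more between the samples than the rest, and were chosen after their values were seen. The polyubiquitin gene UBB had 71.5 CPM in sample 1 and 159 CPM in sample 2. TAGLN, an actin-binding protein of smooth muscle, had 2.51 and 6.77 CPM. NPIPB5 had 16.4 and 36.5 CPM while NPIPB3, of the same family, had 10.02 and 5.35 CPM, and whether reads fit both genes was not tested. The locus annotated as the microRNA gene MIR3648-1 had 24.3 and 7.32 CPM, and whether its reads come from a microRNA was not tested. The kinase gene AKT1 did not differ, with 258 CPM in both, and the glucocorticoid receptor gene NR3C1 had 44.6 and 44.9 CPM. PHLPP1, looked up with them, had 41.6 and 51.6 CPM and passed the binomial test. PHLPP2 had 29.4 and 28.6 CPM and did not pass.

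Replication-dependent histone mRNAs, which end in a stem-loop and not in a poly(A) tail, were near the floor in cells that expressed replication genes at a median of 81.3 CPM. Reads lost between near-identical copies were argued against: the 46 histone genes with at least 80% unique 50-base stretches still had a median of 0.263 CPM, where 8 polyadenylated histone variant genes had 174 CPM. Loss of short transcripts was argued against as the whole cause: the 22 ribosomal protein genes with a principal transcript of up to 600 bases had 0.333 of the median of the 55 longer ones (an earlier form of the test by longest transcript found 0 genes short enough), but the histone genes had only 0.00148 of the median of these 22, and the 15 histone genes longer than 600 bases still had 0.564 CPM. The ratio to the variant genes, 0.00151, goes with enrichment of polyadenylated RNA, a hypothesis that the labels, which speak of total RNA, leave open. It was chosen after the low histone levels were seen and largely restates them, so it adds little support. No biological explanation was tested, since there is only 1 group.

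Some members of lists of broadly expressed genes had few counts beside the rest: 26 of 358 had under 10% of their list's median, from FKBP2 (0.0686 ± 0.0971 CPM) to RPL23A (40.7 CPM), among them RPS10 (1.49 ± 0.752 CPM), RPL17 (2.64 ± 0.600 CPM), PRC1 (1.41 ± 0.0813 CPM), NUSAP1 (1.68 ± 0.891 CPM) and FKBP1B, all named after their values were seen. Near-identical copies elsewhere were argued against as the general cause, with a median of 100% unique 50-base stretches. At least 10% of exonic bases lay in same-strand exons of another gene in 61.5% of them (16 of 26) and in 6.93% of the others (23 of 332; exact Fisher test, 2-sided, p = 4.17e-11), and RPS10 and RPL17 overlap the read-through genes RPS10-NUDT3 and RPL17-C18orf32. Discarding of reads that fit overlapping genes is thus a candidate explanation for part of the list, but the median overlap was only 18.6%, below the 50% set in advance for it as the main cause and above the 10% set against it. It leaves genes with no overlap in GENCODE 29, such as FKBP2, unexplained. The strand setting of the counting is not known, and overlap on either strand was not tested. Either-strand overlap was 61.6% for ATP5ME and 37.1% for CCNE2, which have none on the same strand. It was 0% for FKBP2, FKBP7, FKBPL and MBNL2. No biological explanation was tested.

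Extracellular matrix genes were higher in sample 2 with a median log2 ratio of 0.15, and trends with GC content and transcript length were argued against as the whole cause by a median of 0.12 after their removal, above the highest of 10000 random lists (0.07). The larger share of the mitochondrially encoded genes and XIST in sample 2 lowers the CPM of other genes there and so has the wrong direction; the median of 0.15 without them is no test of it, since leaving them out could only raise the median. Fibroblasts rich in COL1A2, COL3A1, DCN, LUM and POSTN were argued against as well. These 5 genes belong to the matrix list, but 4 were under 1 CPM and so outside its 39 genes. Their median change from sample 1 to sample 2 was -0.0895 CPM, where the matrix list had 5.996 CPM. Fibroblasts that express little of these 5 genes stay open. Of 8 fibroblast markers with at least 1 CPM, 6 were higher in sample 2 and 2 lower. COL1A1 (54.0 and 65.4 CPM), which is also in the matrix list, and FBLN1 (129 and 144 CPM) were higher and passed the binomial test. Cells of another type in general stay open, and a difference in culture may also remain. The 6 fibroblast markers outside the list had a median log2 ratio of 0.0945. Markers of epithelial lines had 0.18, with 10 of 12 higher in sample 2 and none past the test. That median lay inside the central range of random lists matched on mean CPM, -0.098 to 0.219. All 8 fibroblast markers, also at 0.0945, lay inside theirs, -0.112 to 0.174. These medians therefore do not decide whether such cells were present. No biological explanation was tested, because both samples carry the same label.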
